A study of Bombyx mori with 3 samples.

How the data were processed

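RNA pools of egg, pupa and adult silkworms were each hybridised against 1 larval pool on an array of ncRNAs, giving 3 stage tables with 1 pooled sample per stage. Per the labels' protocols, the animals were raised at 25 °C with 14 h of light and 10 h of dark and 70% relative humidity, total RNA was extracted with Trizol, and Cy3 and Cy5 were incorporated during cDNA synthesis. Each table lists 561 spots. These are 132 ncRNAs and 7 probes named AP in 3 spots each, 3 named controls in 12 spots each, and 108 negative spots. Of the negative spots, 48 were blank, 33 held buffer (SSC) and 27 were other negative controls.

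For every spot and scan, the authors deposited a red and a green intensity and a flag. Per the file headers, the red channel is Cy5 and the green channel Cy3, and the column names give the stage in each dye. The median log2 ratio of the ncRNA spots lay between -0.04 and 0.10 in the 6 scans, so the deposited intensities were taken as already normalized between dyes, which no header or label states. The software, the background correction and the normalization method are not given in the sources used here, and neither background nor unnormalized values were used. The authors' deposited log2 ratio per spot equals the mean of log2 stage over larva over the scans whose flag is 0 or above, within 1e-08, in all 408 egg, 382 pupal and 410 adult spots that have one. The direction of each ratio was taken from the column names. The authors' deposited p-value per spot, whose test is not stated, compares technical measurements of 1 pool and was not used to call changes. In the authors' deposited tables it is under 0.05 at 88 of 363 ncRNA spots in egg, 4 of 355 in pupa and 144 of 368 in adult. The authors' deposited value table holds a log2 ratio per ncRNA, with column medians of 0.05 for egg, 0.00 for pupa and -0.02 for adult. It equals the mean of the deposited spot ratios for 125 ncRNAs in egg, 121 in pupa and 125 in adult. The exceptions in each column were Bm-40, whose value differs, and 1 name that has no spots in the stage tables.

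Here the log2 ratio of stage over larva was computed from the deposited intensities of each spot and scan with a flag of 0 or above, without a pseudocount. Spots were averaged within each dye orientation, and the 2 orientations were averaged with equal weight, so that an additive dye effect cancels where both orientations were measured. An ncRNA with kept spots in 1 scan takes its value from that scan. The design fixed before the data were examined foresaw background correction and loess for unnormalized scanner values, and values already normalized were to be used as deposited. No test was run between stages, because each stage is 1 pool, and no p-value was computed. A change was counted at a log2 ratio of at least 1 in size with the same sign in every kept spot and scan. The number of arrays limits the precision, and the SDs are taken over repeated spots of the same probe only.

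The named ncRNAs were set before the data were examined: for each stage, up to 10 with the highest and 10 with the lowest log2 ratio among those that passed this rule, all members of fixed lists of spliceosomal and RNA polymerase III RNAs, ncRNAs past 2-fold with the same sign at all 3 stages, and ncRNAs past 2-fold with opposite signs at 2 stages (up to 5). The names carry no RNA class, so the lists and the planned comparison of ncRNA classes were left out. Names listed at 1.5-fold or under another setting, and those from the unshared pupal scan alone, were picked after their values were seen. Correlations are across ncRNAs, which are not independent replicates. For the shared larval pool, 10000 simulations of unchanged stages drew a larval term and a stage term, which together have the technical SD of 0.19 on the log2 scale, estimated from the difference between dye orientations. For a single scan the SD was enlarged as for 1 measurement in place of a mean of 2.

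The calling step was tested on simulated data with the spot spread of each stage and its dye spread (for pupa, that of egg), with 20 of 132 ncRNAs changed in each of 50 simulations. Changes of 1.5 on the log2 scale were recovered in 100% of cases at every stage, and changes of 0.8, which lie under the threshold, in 2.3% for egg, 0.4% for pupa and 0.7% for adult. False calls numbered at most 0.06 per simulation. The changed ncRNAs were drawn only from those measured in both scans, 104 in egg, 108 in pupa and 112 in adult. These recovery rates therefore leave out ncRNAs measured in 1 scan or none. For pupa both simulated scans held the same change, unlike the deposited pair, whose r was -0.375. Alternatives chosen before the data were examined were median centring, the authors' value table, leaving out the dimmest 25% of spots, the median of repeated spots, each dye orientation alone, thresholds of 1.5-fold and 4-fold, no condition on sign, and a pseudocount of 50 intensity units. Alternatives added after seeing the data were an extra loess fit (span 0.4), keeping flagged spots, leaving out each of the 3 spots in turn, turning the sign of the pupal scan in Cy5, taking pupa from its unshared scan, and leaving out Bm-86. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.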

Results

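Levels of non-coding RNAs (ncRNAs) of 50 to 500 nucleotides were compared across the life cycle of the silkworm Bombyx mori, strain Dazao P50, on a 2-colour array. Egg, pupa and adult were each represented by 1 pooled RNA sample, and a pool of larvae from instars 1 to 5 was the reference in every hybridisation. The egg pool held diapaused and non-diapaused eggs, the pupal pool covered days 1 to 9 of pupation, and the adult pool held male and female moths. Each stage had a table of 2 scans with the dyes swapped, so that the stage was in Cy5 (red) in one scan and in Cy3 (green) in the other. The array carried 132 ncRNAs named Bm with a number, each in 3 spots. The tables gave no sequence, RNA class or genomic position for these names, and 0 of the 132 names occurred in the gene table used here. Between 73.7% and 85.9% of ncRNA spots were kept per scan, with a median stage signal of 1067 to 1643 intensity units in the kept spots. With 1 pool per stage there was no biological replicate and no test between stages. Each error below is the SD over the repeated spots, which is technical, and the ratio to larva leaves out the larva's own spread. Each spot entered the SD as the mean of its kept scans. Where every spot was kept in both scans, the SD leaves out the difference between dye orientations. Where some were not, as for Bm-16 in egg, it includes part of that difference. A change was counted where the log2 ratio was at least 1 in size (2-fold) and had the same sign in every kept spot and scan.

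The egg comparison asked which ncRNAs differed in level between eggs and larvae. Bm-86 was 5.89-fold lower in egg than in larva, with a log2 ratio of -2.56 ± 0.21 (SD, 3 spots), and was the only ncRNA that passed the 2-fold rule in that direction. Another 5 ncRNAs were higher in egg. Bm-158 had a log2 ratio of 1.42 ± 0.14 (2.67-fold), Bm-100 of 1.36 ± 0.08 (2.57-fold) and Bm-160 of 1.30 ± 0.11 (2.46-fold), and they were followed by Bm-183 at 1.26 ± 0.08 (2.40-fold) and Bm-102 at 1.12 ± 0.09 (2.18-fold). Each of these 6 values was larger than its spot SD, which the rule of size and sign makes likely and which adds no support. At the lower threshold of 1.5-fold, with the same condition on sign, 17 ncRNAs were higher and 9 were lower, of 126 measured. The 17 included Bm-37 at 0.92 ± 0.20 and Bm-159 at 0.81 ± 0.09, and the 9 included Bm-16 at -0.77 ± 0.33. Bm-28, Bm-43 and Bm-121 of the 17 and Bm-95 and Bm-110 of the 9 were measured in 1 dye orientation only. A dye effect is not removed from them. Bm-43 rested on 1 spot, and Bm-121 was at 0.72 ± 0.85. Of the 17, Bm-43 and Bm-121 had a larval signal below the 95th percentile of the negative spots in every scan that measured them, and Bm-152, Bm-158 and Bm-176 in 1 of the 2 scans. The other 6 ncRNAs of the array had no kept spot in egg. Across the 104 ncRNAs measured in both scans, which are not independent replicates, the log2 ratios of the dye orientations had a Pearson r of 0.685 and a Spearman rho of 0.568. Bm-86 was at -3.11 with egg in Cy5 and -2.01 with egg in Cy3, and with egg in Cy5 alone 3 ncRNAs passed as lower. Bm-183 was at 0.91 with egg in Cy3 and so did not pass in that scan alone.

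In the adult comparison, Bm-86 was 15.9-fold lower than in larva, with a log2 ratio of -3.99 ± 0.05 (SD, 3 spots). No other ncRNA passed the 2-fold rule as lower. Bm-152 was 2.65-fold higher in adult (1.41 ± 0.18), Bm-140 was 2.40-fold higher (1.27 ± 0.11) and Bm-163 was 2.34-fold higher (1.23 ± 0.03). The larval signal of Bm-152 with adult in Cy3 was 1023, below the 95th percentile of the negative spots (1551), and its log2 ratio was 1.37 with adult in Cy5. At 1.5-fold, 13 ncRNAs were higher and 9 were lower, of 126 measured. Bm-153, 1 of the 13, was measured with adult in Cy5 only, so a dye effect is not removed from it. Among the 13 were Bm-23 at 0.90 ± 0.02 and Bm-135 at 0.67 ± 0.32, and among the 9 was Bm-79 at -0.72 ± 0.08. Of the 13, 5 (Bm-18, Bm-35, Bm-100, Bm-135 and Bm-152) had a larval signal below that percentile in some scan. For 4 of the 9 (Bm-51, Bm-109, Bm-115 and Bm-129) the adult signal lay below the 95th percentile of the negative spots in each scan. Their adult level was therefore not above background by this measure, and the size of their change is open. Bm-104 and Bm-108 lay below that percentile in 1 of the 2 scans. Background is judged by this percentile throughout. The median adult signal of the negative spots was lower, at 107 with adult in Cy5 and 63.5 with adult in Cy3. Bm-129 was at -0.96 ± 0.40, from 3 spots with adult in Cy5 (-1.48) and 1 spot with adult in Cy3 (-0.45), and it counted as lower in the authors' deposited value table, where 2 ncRNAs passed. Between the dye orientations r was 0.880 and rho 0.786 across 112 ncRNAs. The scan with adult in Cy3 is the one that also stands in the pupal table. From the other scan alone, with adult in Cy5, 2 ncRNAs were higher (Bm-152 and Bm-163, with Bm-140 at 0.98) and 3 were lower (Bm-51, Bm-86 and Bm-129). The adult signal of Bm-86 was 1244 with adult in Cy5, above the 95th percentile of the negative spots (792), and 1426 with adult in Cy3, below that percentile (1568), so the size of its change in adult is limited by background.

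**Figure D1:**
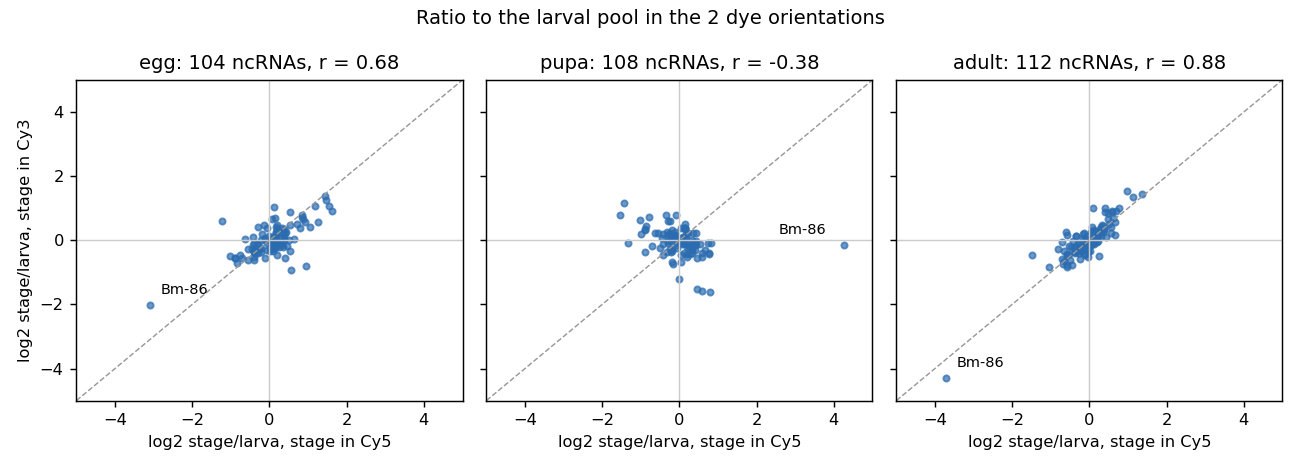
Each point is 1 ncRNA, with its log2 ratio to larva from the scan with the stage in Cy5 on the horizontal axis and from the scan with the stage in Cy3 on the vertical axis, as means over kept spots. Egg and adult lie along the dashed line of equal values (r of 0.685 and 0.880), while the pupal scans run against each other (r of -0.375), and Bm-86 is marked in each panel.

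The pupal comparison rested on a table in which 1 scan was also found in the adult table. The scan labelled as pupa in Cy5 against larva in Cy3 and the scan labelled as larva in Cy5 against adult in Cy3 had the same flag at all 561 spots. Their log2 red over green values differed with an SD of 0.0133 over 363 spots kept in both, against 0.60 to 1.21 for the other 14 pairs of the 6 scans. In addition, the log2 ratios of the scan labelled as pupa in Cy5 ran against the other pupal scan across 108 ncRNAs, with r of -0.375 and rho of -0.432. At the level of spots it also ran against the other scans with the stage in Cy5, with r of -0.458 for egg and -0.850 for adult. Read as adult over larva, the shared scan had r of 0.880 with the other adult scan across 112 ncRNAs. Whether the shared scan holds pupal RNA, and in which direction, is therefore not settled. Pupal values are given from both scans as labelled, with the sign of the shared scan turned, and from the unshared scan. Of these, only the values from the unshared scan include no scan that is also labelled as adult.

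**Figure D2:**
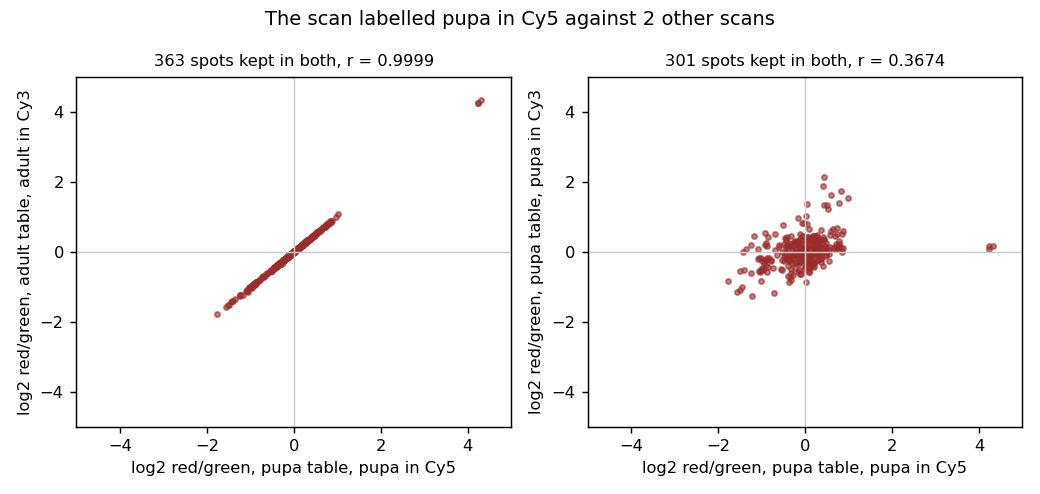
Each point is 1 spot kept in both scans of a panel, with log2 red over green of the scan labelled as pupa in Cy5 on the horizontal axis and of the scan labelled as adult in Cy3 (left, 363 spots) or pupa in Cy3 (right, 301 spots) on the vertical axis. The left panel forms a single line, and the right panel is a wide cloud with an r of 0.367.

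From the unshared scan, with pupa in Cy3, Bm-152 was 2.26-fold higher in pupa than in larva, with a log2 ratio of 1.17 ± 0.08 (SD, 3 spots). In the same scan 4 ncRNAs were lower. They were Bm-51 at -1.63 ± 0.10 (3.09-fold lower), Bm-155 at -1.58 ± 0.50, Bm-128 at -1.52 ± 0.31 (2.86-fold lower) and Bm-16 at -1.20 ± 0.25 (2.29-fold lower, 2 spots). Bm-86 was close to its larval level in this scan, at -0.13 ± 0.05. At 1.5-fold, 9 ncRNAs were higher and 7 were lower, of which 1 (Bm-135) and 3 (Bm-25, Bm-37 and Bm-51) were not above background in the dimmer channel. These values come from 1 dye orientation, so a dye effect is not removed from them, and the pupal signal of Bm-51 (345) lay below the 95th percentile of the negative spots (369).

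With both pupal scans averaged as labelled, which was the design fixed before the data were examined, 0 ncRNAs were higher and 0 were lower in pupa at 2-fold, of 123 measured. At 1.5-fold 1 was higher (Bm-57, measured only in the unshared scan) and 3 were lower (Bm-18, Bm-85 and Bm-163). In the unshared scan alone Bm-18 was at -0.37 and Bm-163 at -0.09, both short of 1.5-fold, and Bm-85 had no kept spot. With the sign of the shared scan turned Bm-18 was at 0.26, Bm-85 at 0.93 and Bm-163 at 0.62, and 10 ncRNAs were higher and 5 lower at 1.5-fold. Bm-86 had the largest mean log2 ratio of the named ncRNAs in pupa, 2.06, from 4.26 in the shared scan and -0.13 in the unshared scan, and so did not pass the condition on sign. At 2-fold with that sign turned, 2 ncRNAs were higher (Bm-140 at 1.16 and Bm-152 at 1.30) and 3 were lower (Bm-51, Bm-86 and Bm-155), with Bm-86 at -2.20. The turned scan is also the one labelled as adult in Cy3 in the adult table, so values with the sign turned combine the unshared pupal scan with the ratios that table gives for adult.

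Set against each other through the larval pool, egg and adult shared 1 ncRNA past 2-fold, Bm-86, which was lower in both. At 1.5-fold they shared 3 ncRNAs among those higher (Bm-100, Bm-140 and Bm-152), where independent lists would share 1.81, and 2 among those lower (Bm-79 and Bm-86), where independent lists would share 0.590. None (0) went in opposite directions. Unchanged stages simulated against a shared larval term of technical size shared 0.0088 higher and 0.0089 lower ncRNAs on average. Independent lists leave out the shared larval pool and the simulation leaves out any change, so neither is a full baseline. Across 122 ncRNAs, the egg and adult log2 ratios had r of 0.512 and rho of 0.294, and without Bm-86 r was 0.307. The simulation gave r of 0.498. The sign was the same in egg and adult for 70 of the 122 (57.4%), against 66.6% in the simulation. The simulated r and share with the same sign follow from the equal size of the simulated larval and stage terms. Neither can serve as a baseline for these data. The covariance without Bm-86 was 0.0596, against 0.0184 in the simulation. No ncRNA (0) was past 2-fold with the same sign at all 3 stages, with pupa as labelled or from its unshared scan, and 1 (Bm-86, lower) was with the sign of the shared scan turned. That turned value counts the scan labelled as adult in Cy3 for pupa as well, and Bm-86 was at -0.13 in the unshared pupal scan. Bm-86 was the 1 ncRNA past 2-fold with opposite signs between stages, between pupa and both egg and adult, and that contrast came from the shared scan.

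An ncRNA was counted as highest at a stage where it exceeded each other stage, larva included, by a log2 difference of at least 1. Of 117 ncRNAs measured at all stages, 3 met this: Bm-158 and Bm-183 in egg, and Bm-86 in pupa. With pupa taken from its unshared scan, 2 of 107 met it, Bm-158 and Bm-183, both in egg. With the sign of the shared scan turned there were again 3, with Bm-86 then highest in larva. That result counts the scan labelled as adult in Cy3 for pupa as well, and Bm-86 was at -0.13 in the unshared pupal scan. Bm-158 was at 0.20 ± 0.06 in adult and, from 1 spot of the unshared scan, at 0.08 in pupa, while Bm-183 was at 0.20 ± 0.05 in adult and -0.38 ± 0.09 in the unshared pupal scan.

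**Figure D3:**
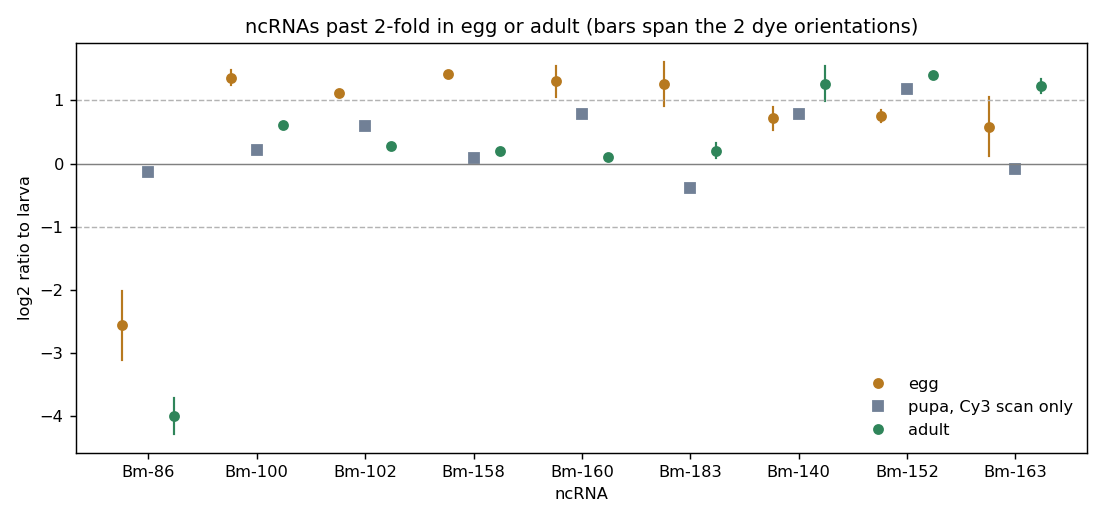
Log2 ratios to larva are plotted on the vertical axis for the 9 ncRNAs past 2-fold in egg or adult, with circles for the mean of the dye orientations, bars from one orientation to the other, and squares for the unshared pupal scan, which has 1 orientation. Dashed lines mark a log2 ratio of 1 in either direction, and Bm-86 lies at -2.56 in egg, -3.99 in adult and -0.13 in pupa. The adult circle of Bm-160 (0.11) comes from 1 spot in 1 dye orientation. Its larval signal of 252 lay below the 95th percentile of the negative spots (1551).

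The array also carried 3 named controls, each in 12 spots. The name ph was not resolved to an RNA. The control for RpL3, a protein of the large ribosomal subunit, was at 0.89 ± 0.26 in egg and -0.27 ± 0.29 in adult. It had no kept spot in the unshared pupal scan. Its value of 0.51 ± 0.28 for pupa came from 7 spots of the shared scan, which also gave -0.53 with adult in Cy3, so it is not a separate pupal measurement. The control for actin A3, a cytoplasmic actin, was at -0.31 ± 0.23 in egg and -0.28 ± 0.30 in adult, the latter from 6 spots. The control named ph was at 0.54 ± 0.20 in egg and 0.84 ± 0.12 in adult, and in pupa at -0.37 ± 0.26 from both scans and 0.26 in the unshared scan.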

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

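The correlations between the scans of a stage were planned before the data were examined, and their use to weigh the scan labels and the other tests in this part were chosen after the results were seen.

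The named controls were not part of the ncRNA comparisons, and a pair of them stood apart from the larval level. The RpL3 control in egg had a log2 ratio of 0.89, with the mean of each of its 12 spots above 0. The ph control in adult was at 0.84, also with the mean of each of its 12 spots above 0. No explanation was tested for either.

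A blank spot in the pupal table, in the scan labelled as pupa in Cy5, had a green intensity of 25789 and a red intensity of 12542 and carried no negative flag. The median of the blank spots in that scan was 64.9 in green and 72.8 in red. In the adult table, the same spot had 31400 in green and 15268 in red in the scan with adult in Cy3. In the other 4 scans the spot was at 25.9 to 71.6 in both channels and was left out by its flag.

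That blank spot is 1 of the features that the scan labelled as pupa in Cy5 and the scan labelled as adult in Cy3 have in common. Separate hybridisations are argued against by the SD of 0.0133 between their log2 red over green values, far below the median spot SD of 0.12 within a scan. The label of pupa in Cy5 is argued against by the r of -0.375 with the other pupal scan, and the label of adult in Cy3 passed the corresponding test with r of 0.880 against the other adult scan. A candidate explanation is that 1 adult scan was entered in both tables, which holds only if the labels of the other pupal and adult scans are right. Under it, the averaged pupal ratio of an ncRNA kept in both scans would be a mean of pupa over larva and larva over adult, and with the sign turned a mean of pupa and adult over larva.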

How the results depend on the processing

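Of 120 recomputed log2 ratios of ncRNAs called at their stage, 104 moved by less than the spot SD, 16 moved further and 0 changed sign. The 16 moved where 1 dye orientation was used alone and, for Bm-86 and Bm-163 in adult, with the extra loess fit. Leaving out a spot or taking the median of repeated spots can hardly move a value past the spot SD, so the 104 adds little support. A call required the same sign in every kept spot and scan. Settings that drop spots or scans, take medians, add a pseudocount or use the value table therefore could not turn a called sign. Leaving out the dimmest 25% of spots moved none of these values. Ranges were -3.11 to -2.01 for Bm-86 in egg, -4.28 to -3.71 for Bm-86 in adult, 0.91 to 1.61 for Bm-183 in egg and 0.98 to 1.55 for Bm-140 in adult. The settings from the 1.5-fold threshold to the authors' value table were planned before the data were examined, and keeping flagged spots, leaving out a spot, turning the sign and leaving out Bm-86 were added after the data were seen. The 1.5-fold threshold gave 17 higher and 9 lower in egg, 1 and 3 in pupa, and 13 and 9 in adult. It also gave 19 highest at 1 stage, with pupa averaged as labelled, so the unsettled stage and direction of the shared scan affect that count. Bm-152 was counted in adult (1.41), but it was at 1.17 in the unshared pupal scan, less than 1.5-fold lower. The 4-fold threshold left 0 higher in egg, 0 higher in adult and 1 highest at 1 stage. That 1 was Bm-86 in pupa, from 4.26 in the shared scan and -0.13 in the unshared scan. With the sign of the shared scan turned, the pupal value of Bm-86 was -2.20. That value averages the -0.13 of the unshared scan with the scan that gave -4.28 for adult in Cy3, so it is not a separate pupal measurement. With the stage in Cy5 alone, 3 were lower in egg, 1 was higher and 5 lower in pupa, and 3 were lower in adult. In that setting 5 were highest at 1 stage, and pupa was the shared scan alone. The 1 higher and 5 lower in pupa therefore rest on a scan whose stage and direction are not settled. The same holds for Bm-86, counted as highest in pupa (4.26), and Bm-163, counted in adult (1.12, against -1.34 in pupa). With the stage in Cy3 alone, 1 was higher and 4 lower in pupa, 5 were higher in adult, and 1 was highest at 1 stage. Without a condition on sign 1 was higher in pupa (Bm-86). The authors' value table gave 2 lower in adult, with Bm-129 weighted by spot. Keeping flagged spots gave 2 lower in egg and an r of 0.765 between adult scans. Without spot 3, 2 were lower in adult. With the sign of the pupal scan in Cy5 turned, 2 were higher and 3 lower in pupa, and r between its scans was 0.375. Without Bm-86, the egg and adult r was 0.307. Except for the thresholds, the condition on sign, the value table and the turned sign, whose effect follows from their construction, the cause was not tested. Not run for lack of background, unnormalized or class values were other background corrections, no normalization, centring on snRNAs and all settings of ncRNA classes. Signal over background limits Bm-86, Bm-51 and Bm-129 in adult and Bm-51 and Bm-37 in pupa, among others.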

Other observations

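The simulation of the egg and adult covariance was planned before the data were examined, and leaving out Bm-86 and the other tests in this part were chosen after the results were seen.

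In the unshared pupal scan, 4 of the 9 ncRNAs past 1.5-fold higher were also past it in egg (Bm-102, Bm-140, Bm-152 and Bm-160), where independent lists would share 1.25 and unchanged stages simulated against a shared larval term of technical size 0.0213. In adult, 4 of the 8 that were measured there were also past it (Bm-23, Bm-135, Bm-140 and Bm-152), against 0.954 and 0.0156. Among those lower, 1 was shared with egg (Bm-16), against 0.454 and 0.0181, and 1 with adult (Bm-51), against 0.578 and 0.0195. Bm-51 was not above background in pupa or adult, and Bm-135 was not in pupa or in 1 adult scan. The larval signal of Bm-152 was not above background in 1 egg scan and 1 adult scan. In the unshared pupal scan its larval signal was 6097 and its pupal signal 13515, so the intensity read from the larval pool differed between scans. With pupa taken from its unshared scan, Bm-140 and Bm-152 were past 1.5-fold higher at all 3 stages. For Bm-140 in egg this depended on 1 spot with egg in Cy3 (0.90), as its 3 spots with egg in Cy5 averaged 0.53, short of 1.5-fold. With both pupal scans averaged as labelled, Bm-140 was at -0.38 and Bm-152 at -0.13 in pupa. Bm-140 was at 0.71 ± 0.27 in egg, 0.78 ± 0.25 in the unshared pupal scan and 1.27 ± 0.11 in adult, and Bm-152 was at 0.75 ± 0.09, 1.17 ± 0.08 and 1.41 ± 0.18. All of these ratios share the larval pool, so a low level of both ncRNAs in that pool alone would also put them above larva at every stage.

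In the opposite sense, 2 ncRNAs past 1.5-fold higher in egg, Bm-37 and Bm-159, were past it lower in the unshared pupal scan. Bm-159 was at 0.81 ± 0.09 in egg and, from 2 spots, at -0.68 ± 0.40 in pupa. Bm-37 was at 0.92 ± 0.20 in egg, and its pupal value came from 1 spot that was not above background. Across 105 ncRNAs the unshared pupal scan had r of 0.390 with the scan of adult in Cy5, and across 101 ncRNAs r of 0.200 with egg in Cy5. Without Bm-86 r was 0.484 for adult and 0.220 for egg. By rank, with Bm-86 kept, rho was 0.452 for adult and 0.095 for egg, so the egg pair showed little of a trend across the array. Simulated unchanged stages gave r of 0.498 for each pair, a value set by the equal size of their larval and stage terms. The covariance without Bm-86 was 0.0986 for adult and 0.0558 for egg, against 0.0369 and 0.0368 in the simulation, which reached the observed value in 0 and 175 of 10000 draws. The size of the larval term was assumed from the technical spread, so the source of the excess stays open.

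Bm-86 was lower in egg and adult than in larva. A dye effect is argued against as the whole cause, because the part of the log2 ratio that turned with the dye was at most 0.214 of the mean change. An excess of Bm-86 in the larval pool alone would also lower pupa against larva. The unshared pupal scan was at -0.13, which goes against it, but 1 scan in 1 dye orientation does not exclude it. The shared scan also stands in the adult table and neither its stage nor its direction is settled, so it was not used here for pupa. A stage difference, with Bm-86 more abundant in larvae than in eggs and moths, may also account for it and was not tested beyond 1 pool per stage.

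The egg and adult log2 ratios had a covariance of 0.0596 across ncRNAs without Bm-86. The share with the same sign was 57.4% of 122. The simulated share (66.6%) was fixed by equal larval and stage terms, so the 2 shares decide nothing. A shared larval term of technical size gave 0.0184 on average, and 0 of 10000 simulations reached the observed value. A larval term with an SD of 0.24 would be enough to give the observed covariance, and 1 larval pool gives no measure of how larval pools vary. A shared change of egg and adult and a departure of this larval pool therefore cannot be told apart.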
